A study of Mus musculus with 2 samples.

How the data were processed

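The series holds 2 one-colour microarrays, 1 of WT and 1 of Gata2 CKO collecting duct cells of mice of 8 weeks, whose Gata2 deletion was induced with doxycycline for 4 weeks from an age of 4 weeks. The CKO label gives 1 floxed and 1 null allele of Gata2 with Pax8-rtTA and Tet-Cre, so tubule deletion and loss of 1 allele elsewhere are not separated, and the WT label gives no transgene. Per the labels' protocols, total RNA was extracted from cells purified with DBA lectin and magnetic beads, and 50 ng of it was amplified and labelled with Cy3. The design text gives 3 mice per genotype and the names of the arrays describe mixtures, but no label states outright that the RNA of the 3 mice was pooled.

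The deposited files hold the scanner output of each array as spot intensity on a linear scale. Per the file headers, the intensities were extracted with Agilent Feature Extraction 10.7.3.1, which subtracted the background with spatial and multiplicative detrending, and the probes were placed on mm9. Both arrays were on 1 slide and in 1 scan, so slide and scan do not separate the genotypes. What normalization the authors used between the arrays is not given in the sources used here.

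Each array had 45018 spots, 43379 of them not controls, and 0 were saturated. Outlier flags removed 66 spots of the WT array and 73 of the CKO array. The main value was log2 of the processed signal minus the 75th percentile of its array. Spots of 1 probe were averaged on the log2 scale, and 245 of the 41174 probes were printed 10 times. The lowest signal of a spot well above background was 12.0 on the WT array and 11.6 on the CKO array, and the negative controls had medians of 2.67 and 2.53. A gene took the value of its probe of highest mean signal among those well above background on at least 1 array. Where it was well above background on 1 array only, the difference is a bound, taken against the lowest signal well above background or the signal of the dim probe, whichever was higher, and given as "at least". List medians and counts of genes include such bounds. By this rule 395 genes were measured on the CKO array only and 893 on the WT array only. Over probes well above background on both arrays, the Pearson correlation across probes, which are not replicates, was 0.984.

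The RefSeq accession of 26876 probes was found in a table of the assembly GRCm38.p6, used for names only, and 2672 probes took another symbol from it than the file's own, which was kept otherwise. Coordinates are those of the files. Whether a probe lies in a coding exon or an untranslated region was not analysed here.

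With 1 array per genotype no test was run and no p-value is given. Genes were counted by a fixed size of 2-fold. For each of 33 gene lists, fixed before the data were examined, the median difference was placed among those of 10000 random lists of the same size, matched on mean signal in 20 bins, and a list was called apart outside the central 95% of these. The genes named are Gata2, the 12 genes with the largest difference in each direction among named genes measured on both arrays, the 3 with the largest bound on each array only, every measured principal cell gene, and up to 4 members of each other list, those at least 2-fold apart where there were any. Some genes that this rule takes are not reported here. Exceptions are marked as named after their values were seen. The spot error is that of the scanner software, combined over both arrays. It, the spread of repeated spots and that of different probes of a gene cover the measurement on these arrays only, not mice, purification or labelling, and the number of arrays limits the precision.

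The steps were tested on simulated data made from the 18579 genes of the WT array with known changes. With the noise of repeated spots 1 of 18379 unchanged genes passed 2-fold, and with the spread between probes of a gene 3 did. Of 100 genes changed 3-fold, 100% and 98.0% passed 2-fold in the right direction, and of 100 changed 1.5-fold 0% and 4.0% did. Of 100 lists of 20 unchanged genes, 7.0% and 6.0% fell outside the random range, and of those shifted by −0.3, 100% and 98.0% fell below it. The changed genes were drawn from the brighter genes of the WT array only, and the noise followed a normal distribution. These shares do not cover dimmer changed genes or probes of 1 gene that disagree strongly, and they leave out differences between mice.

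The alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, cyclic loess, scaling on the median of probes well above background, other filters on dim probes, the mean over a gene's probes, and keeping flagged or leaving out saturated spots. Scaling on 8 spike-in control transcripts well above background was added after seeing the data. The analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.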

Results

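Gene expression was measured in collecting duct cells of adult mouse kidney, the cells that line the last segment of the nephron, from wild-type (WT) mice and from mice in which the transcription factor gene Gata2 had been deleted in renal tubules (Gata2 CKO). By the genotype label the CKO mice carried 1 floxed and 1 null Gata2 allele with Pax8-rtTA and Tet-Cre, so that cells outside the tubules, too, had 1 allele fewer than those of WT mice. Cells were purified with Dolichos biflorus agglutinin (DBA), a lectin that binds collecting duct epithelium, and magnetic beads. Each genotype was represented by 1 one-colour array. The series describes 3 mice per genotype and the names of the arrays describe mixtures. No difference below has a replicate check, and no test across mice was possible. All differences are CKO minus WT on the log2 scale, after each array was set to its 75th percentile. Spot errors are those of the scanner software for the spots alone. The 75th percentile signal was 314 on the WT array and 250.1 on the CKO array, and 64.1% and 62.4% of the spots were well above background. In all, 18972 genes were measured on at least 1 array, 17684 of them on both.

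The first comparison asked what the arrays show of the deleted gene itself. Gata2 was lower on the CKO array by both of its probes, at −0.37 ± 0.20 (spot error), or 77.2% of the WT level, and at −0.32 ± 0.20, or 80.3%. The 60-base probes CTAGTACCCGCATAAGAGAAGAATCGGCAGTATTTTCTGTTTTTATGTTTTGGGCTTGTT and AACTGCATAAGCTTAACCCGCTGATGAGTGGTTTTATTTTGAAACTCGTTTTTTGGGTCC lie on chromosome 6 (mm9) at 88156835 to 88156894 and at 88156362 to 88156421, at positions 3051 and 2578 of the transcript as the files number them. The labels do not say which exons were deleted, so probes this far along the transcript may lie outside the deleted part and then check nothing about the labels.

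The next comparison asked which genes differed between the genotypes. In the CKO cells 282 genes were at least 2-fold higher and 538 at least 2-fold lower, and 24 and 140 were at least 4-fold higher and lower. The named gene with the largest difference upward was Hsd3b2, of the 3-beta-hydroxysteroid dehydrogenase family, at 5.85 ± 0.29. Another of its probes, also well above background on both arrays, gave 2.98, and near-identical family members leave its identity uncertain. Edn3, which encodes endothelin 3, was higher by 3.94 ± 0.23, with 3.84 at its other probe. Mid1 was higher by 2.90, Celf3 by 2.83, Nefl, the light neurofilament subunit, by 2.08, and Phospho1 by 2.05. Lrrc31 at 2.03, Atp6v1b1, the B1 subunit of the vacuolar proton pump, at 1.94 ± 0.20, Rcor2 at 1.93, Igf2bp1 at 1.90 and Slc12a2, the Na-K-2Cl cotransporter NKCC1, at 1.89 followed. Another probe of Igf2bp1 gave 1.13, and Atp6v1b1 lies within 20 Mb of Gata2 on chromosome 6. Grem1, a BMP antagonist, was well above background on the WT array only and at least 23.0-fold lower on the CKO array. Camk2a was at −4.16, the keratin gene Krt6a at −4.12, Lyzl1 at −3.76, Col13a1 at −3.60, and Cd5l, a protein secreted by macrophages, at −3.57. Nat3 was at −3.54, Hormad1 at −3.39 and the inhibin subunit Inhbb at −3.39. Other probes of Camk2a, Col13a1, Hormad1 and Inhbb were well above background on neither array, with WT signals of 7.92, 2.56, 7.36 and 14.9. The probes used had WT signals of 391, 305, 1521 and 1877. Each of these falls thus rests on 1 probe whose WT signal the other probe did not share, which leaves the fall of the gene uncertain. Sox5 at −3.53 and Agap2 at −3.49 were uncertain too, because their other probes gave 0.20 and 0.10. Zfp385b was at −3.54, and its other probes well above background on both arrays gave −2.23, −0.42 and 0.47. Ifi202b, whose expression differs between mouse strains, was at least 17.3-fold higher on the CKO array. Ptchd3 was higher by at least 3.46 and Tmod4 by at least 2.99, and none of these 3 genes was well above background on the WT array. Trdn was at least 17.8-fold lower and Pabpc6 at least 12.9-fold lower, both well above background on the WT array only. The other probes of Trdn were well above background on neither array, with WT signals from 2.86 to 3.15 against 262 at the probe used, so its fall is uncertain in the same way.

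Spots of 1 probe printed 10 times gave a standard deviation of the difference from 0.18 in the dimmest to 0.025 in the brightest of 5 groups of probes. Different probes of 1 gene gave a root mean square standard deviation of 0.27 over 5308 genes. Agreement between probes was counted over probes well above background on at least 1 array. Genes with 1 such probe, among them Camk2a and Inhbb, were left out. Of the 132 lower genes with 2 or more such probes, 54 were at least 2-fold lower by every probe and 28 had a probe of opposite sign. Of the 40 such higher genes, 16 were at least 2-fold higher by every probe and 3 had a probe of opposite sign. Of the 79 genes named by rule that were at least 2-fold apart, 27 fell short of 2-fold with normexp. They were Phospho1, Igf2bp1, Pde4d, Adcy4, Pvalb, Cldn1, Nphs1, Podxl, Vwf, Ptprb, Ren1, Pdgfrb, Fbln5, Itgam, Cd8a, S100a9, Hba-a1, Krt15, Mmp7, Cxcl1, Ciita, Krt19, Tgfb3, Egr2, Klf4, Slc16a3 and Cyp4b1. Lrp2 and Podxl fell short with the mean of their probes, and Klk1, Slc6a12 and Slc16a3 with spike-in scaling. The split of higher and lower genes depended on the processing. It was 206 and 642 after cyclic loess and 65 and 204 after normexp, whose offset shrinks the differences of dim genes. It was 58 and 1642 when the spike-in control transcripts were set equal, a choice made after seeing the data that moved all differences by −0.55 and the median of all genes from 0.04 to −0.50. Higher and lower below mean above and below 0 on the 75th percentile scale, not above and below the median of all genes.

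**Figure D1:**
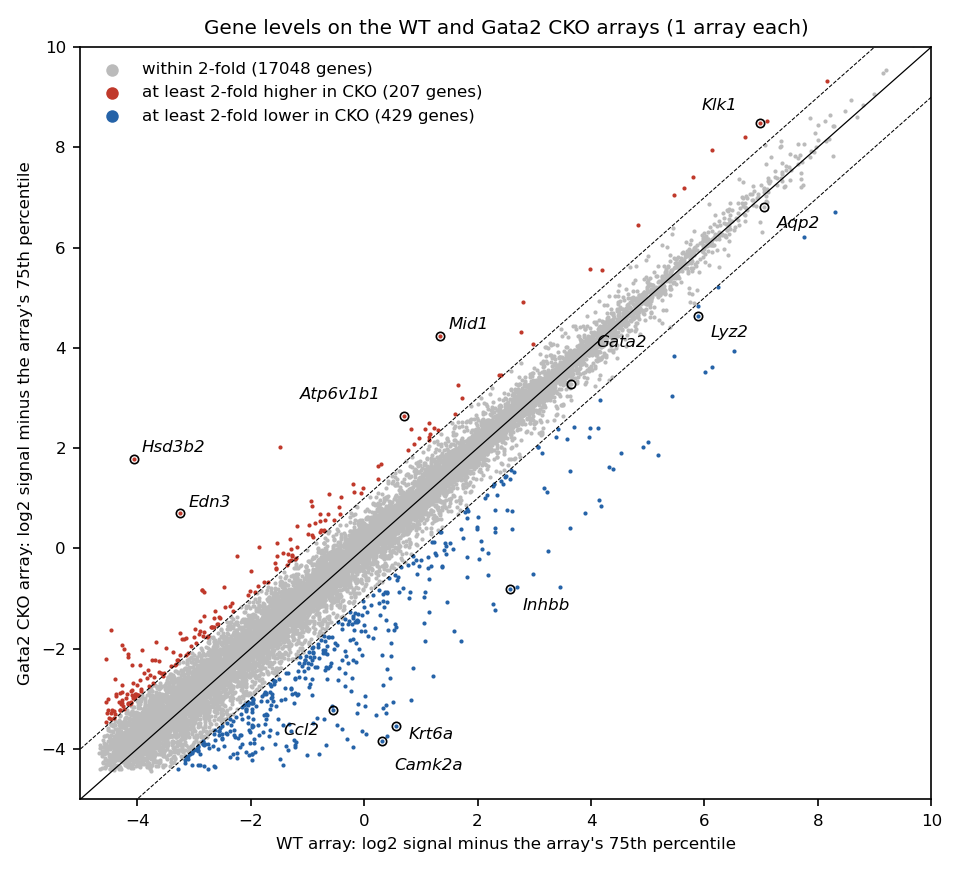
Level of each of the 17684 genes well above background on both arrays, on the WT array (x axis) and the Gata2 CKO array (y axis), as log2 signal minus the array's 75th percentile, with 1 array per genotype and dashed lines at 2-fold. Of these genes 207 lay at least 2-fold above and 429 at least 2-fold below the diagonal, with Hsd3b2 and Edn3 farthest above it and Camk2a and Krt6a among those far below.

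The collecting duct consists of principal cells, which take up water and sodium, and intercalated cells, which move acid and base. The next comparisons asked how genes of each type differed. Principal cell genes were lower in the CKO cells, with a median of −0.28 over 19 measured members, below all of 10000 random lists of the same size and signal (whose central 95% ran from −0.04 to 0.15). Of these members 13 were lower and 6 higher, and 1 was at least 2-fold lower. That gene was Stc1, stanniocalcin 1, at −1.74 ± 0.21, with its 3 probes between −1.74 and −1.49. Sgk1, the aldosterone-induced kinase, was at −0.98, Npnt at −0.70, and Hsd11b2, which inactivates glucocorticoids, at −0.61. Ptgs1 was at −0.60 and the vasopressin V2 receptor Avpr2 at −0.57, each ± 0.20. The sodium channel subunits Scnn1g, Scnn1a and Scnn1b were at −0.50, −0.28 and −0.18, the potassium channel Kcnj1 at −0.48 and the water channels Aqp3 and Aqp2 at −0.43 and −0.25. The differences of Aqp2 and Scnn1a were barely larger than the spot error of 0.20, and those of Scnn1b, Fxyd4 at −0.09, Nedd4l at 0.01 and Slc14a2 at 0.07 were smaller. The software gave much the same error, 0.20, to all these bright genes, so it does not rank them. Repeated spots had a standard deviation of 0.025 in the brightest group of probes, and different probes of 1 gene one of 0.27. The water channel Aqp4, at 0.62 by 3 probes from 0.62 to 0.63, the mineralocorticoid receptor Nr3c2 at 0.48, Elf5 at 0.47 and Gata3 at 0.30 were higher. The median was −0.34 with normexp and −0.37 with quantile normalization.

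Intercalated cell genes were higher in the CKO cells, with a median of 0.62 over 23 members, above all 10000 random lists (−0.04 to 0.14). Of these, 20 were higher and 3 lower, with 1 at least 2-fold in each direction. Atp6v1b1 was at 1.94 and the carbonic anhydrase Car15 at −1.75 ± 0.20. Other members, named after their values were seen, were the transcription factor Dmrt2 at 0.95, the oxoglutarate receptor Oxgr1 at 0.94, the anion exchanger Slc4a1 at 0.91, Aqp6 at 0.90 and pendrin, Slc26a4, at 0.79, markers of acid-secreting and of bicarbonate-secreting cells alike. Car2 and Rhbg, at 0.06 each, did not differ by more than the spot error, and Rhcg and Slc26a7 were at −0.21 and −0.23. With spike-in scaling the median came to 0.07, against −0.50 for all genes.

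**Figure D2:**
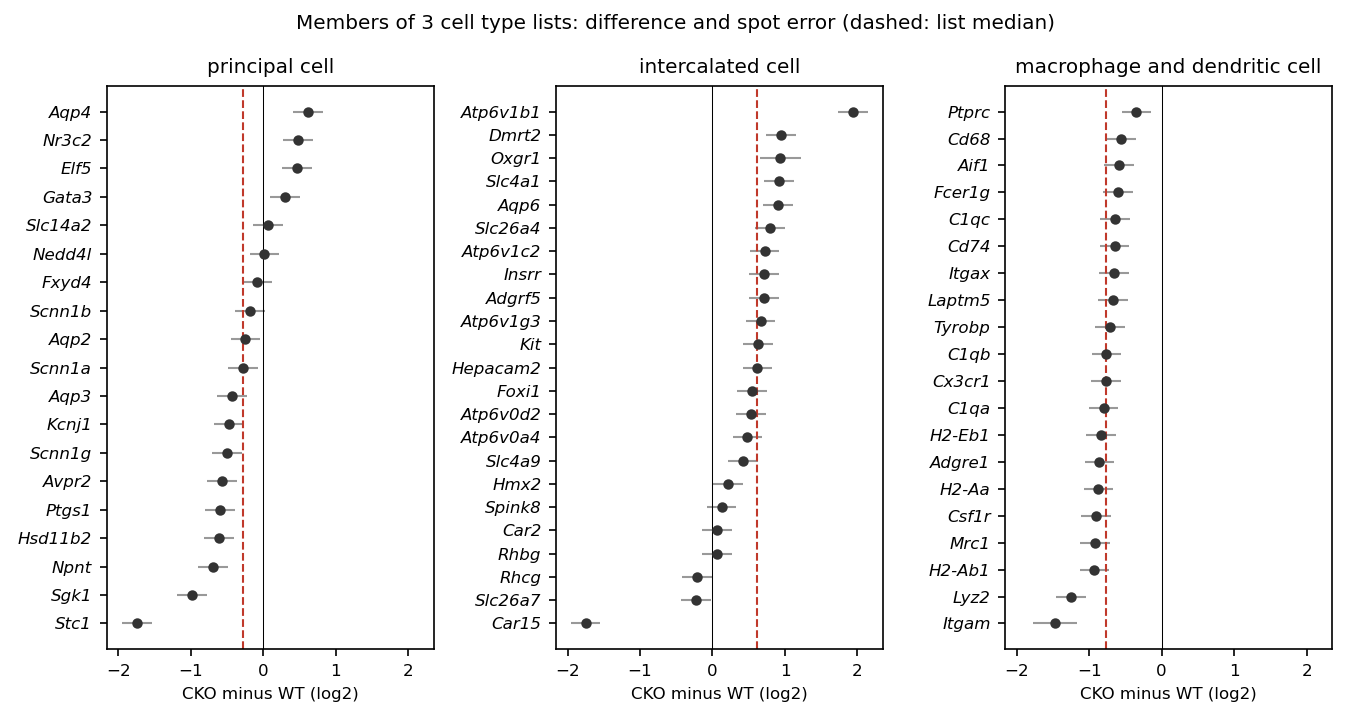
Difference between the Gata2 CKO and WT arrays (x axis, log2) of each measured member of the principal cell, intercalated cell and macrophage and dendritic cell lists, 1 point per gene, with bars for the spot error of the scanner software and a dashed line at the list median. The medians were −0.28, 0.62 and −0.77, and Stc1 and Car15 lie apart from the other members of their lists.

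Genes of vasopressin and cAMP signalling, the pathway that controls water reabsorption in principal cells, had a median of −0.03 over 28 members, at percentile 5.75 of the random lists, but below their range at −0.06 with normexp and −0.04 with the mean of a gene's probes. Pde4d was at 1.63 ± 0.30, with 0.40 at another of its probes and at least 1.47 at a probe well above background on the CKO array only, and the adenylate cyclase Adcy4 at −1.04 ± 0.34, both dim. The other 26 members lay within 2-fold. Genes of aquaporin 2 trafficking were also inside the random range, with a median of 0.00 over 22 members, among them Msn at −0.99, Hspa8 at −0.64, Rab11fip2 at 0.39 and Vamp2 at 0.26. Other probes of Msn gave −1.24 and −0.16 and those of Vamp2 0.73 and 0.77. Collecting duct transcription factors had a median of 0.27 over 22 members (percentile 99.99), 18 of them higher, with Klf5 at 0.93, Emx1 at 0.57 and Foxi1 at 0.55 and none 2-fold apart. The list of GATA factors and their partners had a median of −0.29 over 12 members (percentile 0.07), of which 7 were lower, and one of 0.00, inside the random range, with normexp. The dim genes Gata4 and Tal1 were at −0.90 and −0.81, and Gata1 was at 0.53. Zfpm2 was at least 1.81-fold lower by 1 probe, on the WT array only, and higher by at least 0.85 by another, on the CKO array only. Osmotic response genes had a median of 0.11 over 18 members (percentile 87.0). The betaine transporter Slc6a12 was at 1.36, the taurine transporter Slc6a6 at −1.28 and the heat shock genes Hspa1b and Hspa1a at −1.63 and −1.56. Ion transport ATPases, chloride channels and regulators had a median of 0.04 over 22 members (percentile 48.1), with Fxyd2 at 0.76, Fxyd5 at −0.73 and Kcnmb4 at least 1.59-fold lower.

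Markers of macrophages and dendritic cells and genes of cytokines and of injury were lower in the CKO cells. All 20 macrophage and dendritic cell genes were lower, with a median of −0.77 (percentile 0), including Itgam at −1.47 ± 0.30 and lysozyme, Lyz2, at −1.26 ± 0.20. Cytokines and targets of NF-kB were lower in 21 of 21 members, with a median of −0.66 (percentile 0; −0.43 with normexp), and 6 were at least 2-fold lower. Among these were the chemokines Ccl2 at −2.68 ± 0.25 over 10 spots, Cxcl10 at −1.90 and Cxcl1 at −1.65 and the adhesion molecule Icam1 at −1.53. Tubular injury genes had a median of −0.83 over 21 members (percentile 0), though −0.25 with normexp; 18 were lower, and 9 were at least 2-fold lower. Among these were fibrinogen beta, Fgb, at −2.67, Vcam1 at −1.98, ceruloplasmin, Cp, at −1.98 and Mmp7 at −1.77. Antigen presentation genes were lower in 17 of 18 members, with a median of −0.53 (percentile 0) and Ciita at −1.30, and 4 of the macrophage genes belong to this list too. Interferon response genes had a median of −0.03 over 22 members (percentile 11.1), with Gbp2 at −0.86, Bst2 at −0.53, Isg15 at 0.66 and Ifi44 at 0.58. Genes of lymphocytes, mast cells and neutrophils had a median of 0.00 over 10 members (percentile 33.6), although Cd8a was at least 10.1-fold and S100a9 at least 2.87-fold lower.

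Of the lists of other kidney cells, thick ascending limb and loop lay above its random range and distal convoluted and connecting tubule inside it. The rest lay below theirs in the main setting, as the macrophage genes above did, at −0.77. The fibroblast, pericyte and smooth muscle list had a median of −0.63 over 16 members (percentile 0), though −0.15 with normexp, and 13 were lower, with vimentin, Vim, at −1.53, Pdgfrb at −1.47 and Fbln5 at −1.13. In the same list renin, Ren1, was well above background on the CKO array only and at least 4.83-fold higher, but another of its probes, also on the CKO array only, gave a bound of 0.40, and Ren1 is near-identical to Ren2. Endothelial genes had a median of −0.34 over 19 members (percentile 0.03) but of −0.01 with normexp, and 18 were lower, with Vwf at −1.78 and Ptprb at −1.48. Podocyte and parietal genes had one of −0.50 over 13 members (percentile 0.02; −0.32 with normexp), and 12 were lower, with Cldn1 at least 5.95-fold lower, Wt1 at −1.72, Nphs1 at −1.23 and Podxl at −1.21. Another probe of Podxl gave 0.22. Proximal tubule genes had a median of −0.22 over 26 members (percentile 0.01; −0.10 with normexp), and 17 were lower, with Slc4a4 at −3.12 and Lrp2 at −1.58. Other probes of Lrp2, also well above background on both arrays, gave −1.20 and −0.26. Thick ascending limb and loop genes had a median of 0.30 over 15 members (percentile 99.9), of which 10 were higher and 5 lower and none 2-fold apart, among them Cldn16 at 0.98, Kng2 at 0.85 and Cldn10 at 0.82. Distal convoluted and connecting tubule genes had a median of 0.13 over 16 members (percentile 90.3). Their median was 0.15 and above the random range with normexp, but 0.05 and inside it with cyclic loess. The kallikrein Klk1 was at 1.51 and parvalbumin, Pvalb, at −1.40. The 4 measured red blood cell genes had a median of −0.67 (percentile 0.16), but one of 0.24, inside the random range, with no filter on dim probes, with Hbb-bt at −1.53 and Hba-a1 at −1.30. The 8 urothelium genes had one of −0.39 (percentile 0.83), with Krt15 at −1.87, and 5 were lower. Their median was −0.05 with normexp, and −0.10 on probes of both arrays and −0.14 with no filter, the last 2 inside the random range.

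Genes of the extracellular matrix and fibrosis had a median of −0.36 over 22 members (percentile 0), beside the −0.63 of the fibroblast, pericyte and smooth muscle list. Of the 22 matrix genes, 16 were lower and 6 higher, and 6 were at least 2-fold lower, including Nid1 at −2.13, Sparc at −2.10, Tgfb3 at −1.46 and Ccn1 at −1.19. Immediate early and dissociation response genes, which the isolation of cells can induce, had a median of −0.45 over 23 members (percentile 0), 17 of them lower, with Egr2 at −1.11 and Klf4 at −1.08 beside the heat shock genes named above. Cell cycle genes were lower in 18 of 21 members, with a median of −0.32 (percentile 0.01; −0.12 with normexp) and Ccna2 at −0.84, Cdkn1a at −0.74, Cdk1 at least 1.64-fold lower and Ccnd1 at −0.53. Junction genes and epithelial keratins had a median of −0.11 over 21 members (percentile 0.19; −0.17 with quantile normalization), 14 of them lower, with Cldn2 at −2.14 and Krt19 at −1.35. Unfolded protein response genes had a median of −0.07 over 20 members (percentile 1.03), 12 of them lower, but one of −0.04, inside the random range, with the mean of a gene's probes, with Edem1 at −0.50, Trib3 and Hspa5 at −0.25 and Atf4 at −0.23. Oxidative phosphorylation genes were higher in 26 of 27 members, with a median of 0.18 (percentile 99.9) and Cox7a2 at 0.30, Ndufb9 at 0.29 and Uqcrc1 and Ndufs3 at 0.28, little above the spot error. Inside the random range were glycolysis and hypoxia genes at 0.11 over 24 members (percentile 87.8) with Slc16a3 at 1.15, sterol synthesis at 0.02 over 20 (percentile 40.1) with Fdps at 0.25 and −0.37 by its 2 probes, and ribosomal proteins at −0.03 over 24 (percentile 2.71) with Rps14 at −0.19. The ribosomal proteins lay below the range with cyclic loess, at −0.07, with both other filters and with the mean of a gene's probes. Sex-linked genes had a median of 0.10 over 9 members (percentile 73.1) with Eif2s3y at 0.56 and Ddx3y at −0.17. Sex-biased kidney genes had one of −0.08 over 9 members (percentile 11.6), or −0.26 and below the range with no filter, with Cyp4b1 at −1.34. The labels give mixed sexes for both genotypes. The sex-linked list holds genes of the X and of the Y chromosome, so its median does not measure the balance of the sexes.

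Of the 33 lists, 17 lay below and 4 above the range of the random lists, against 1.65 expected outside it for unrelated genes. The lists share genes, and the genes of 1 list can vary together between any pair of RNA samples, so this describes these 2 arrays and not the genotypes. With spike-in scaling the medians of the collecting duct transcription factors, the thick ascending limb and loop list and oxidative phosphorylation turned to −0.28, −0.25 and −0.36, all still above the −0.50 of all genes.

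**Figure D3:**
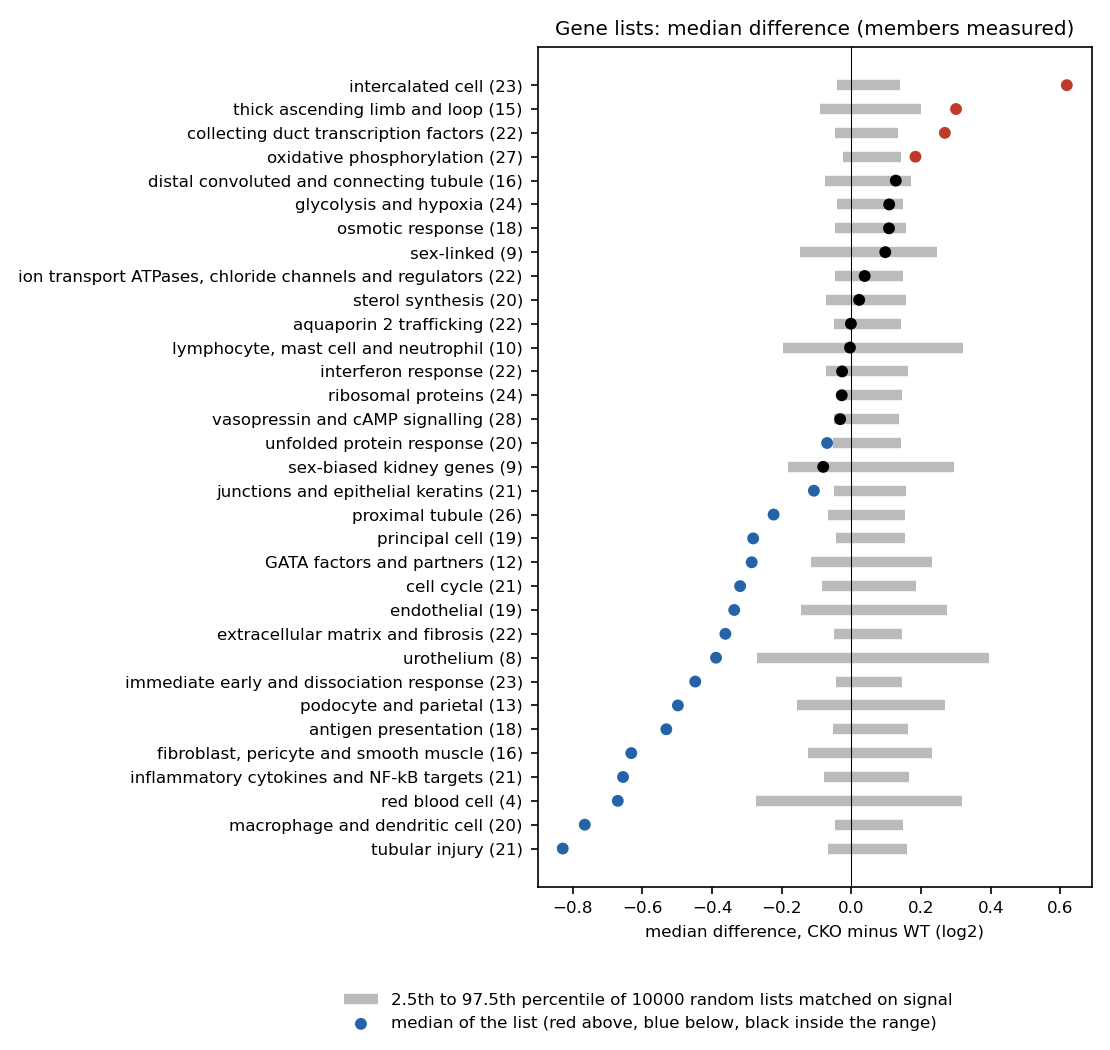
Median difference between the Gata2 CKO and WT arrays (x axis, log2) of each of the 33 gene lists, with the number of members measured in brackets and grey bars for the central 95% of 10000 random lists matched on signal. The intercalated cell list lies farthest above its range, at 0.62, and the tubular injury list has the lowest median in this main setting, at −0.83, though not with normexp.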

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

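All alternatives were fixed before the data were examined except spike-in scaling, which was chosen after seeing the data. No paired analysis was possible because each genotype had 1 array, and for the same reason no replicate could be left out. Under the alternatives fixed beforehand, 1175 of 1274 values of named genes moved by less than their spot error, 99 by more, and 0 changed sign at 2-fold or above. Of 297 list medians, 260 moved by less than the standard deviation of the random lists, 35 by more, and 2 of lists outside the random range changed sign. Counting lists inside the range and near 0 too, 11 medians of 8 lists changed sign. With normexp the medians of several lower lists shrank, from −0.83 to −0.25 for tubular injury, from −0.63 to −0.15 for fibroblast and pericyte and from −0.34 to −0.01 for endothelial genes, all still below the random range. The counts of genes at least 2-fold higher and lower, 282 and 538, were 65 and 204 with normexp, whose offset shrinks differences of dim genes by construction, 1214 and 1244 with no filter on dim probes, and 58 and 1642 with spike-in scaling. The lower share of these genes was 65.6%, against 75.8% with normexp, 75.7% with cyclic loess, 50.6% with no filter and 96.6% with spike-in scaling. With normexp 65 of the 65 higher and 199 of the 204 lower genes were among those of the main setting. The principal cell median, −0.28, was −0.34 with normexp and −0.37 with quantile normalization, the intercalated one, 0.62, was 0.49 with normexp, and both stayed outside the random range under all 10 alternatives. Spike-in scaling and scaling on the median shift the random lists by the same amount, and no spot was saturated, so these alternatives could hardly change that. The vasopressin and cAMP median, −0.03, was 0.017 with no filter, and its place inside the random range was lost with normexp and with the mean of a gene's probes. The list of GATA factors came to 0.0007 with normexp and red blood cell genes to 0.24 with no filter, and both then lay inside the random range. Urothelium genes lay inside it under both other filters and unfolded protein response genes with the mean of a gene's probes. The distal convoluted and connecting tubule list left it with normexp, sex-biased kidney genes with no filter, and ribosomal proteins with cyclic loess, both other filters and the mean of probes. Spike-in scaling gave −0.92 for Gata2, −0.83 for principal cell, 0.073 for intercalated cell and −0.58 for vasopressin and cAMP genes, and turned collecting duct transcription factors to −0.28, thick ascending limb and loop to −0.25 and oxidative phosphorylation to −0.36. It subtracts 1 number from every gene, so the order of genes and lists did not move. For the other changes the cause was not tested. Leaving out saturated spots moved nothing, since there were 0, and keeping flagged spots moved neither count of 2-fold genes. Scaling on the median of probes well above background shifted the differences by −0.0056 only. The counts of values that moved by less than their spread include these settings, which could hardly move a value, and so overstate stability. The spot error of bright genes, 0.20, is also a wide yardstick beside the 0.025 of repeated bright spots. Dim genes are the least certain: repeated spots had a standard deviation of 0.18 in the dimmest group of probes against 0.025 in the brightest.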

Other observations

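The tests on cell type lists, 5' signal, random loss in amplification and strain genes were set after the results they bear on had been seen, and the conditions for 5' loss, for scaling, for the shares of principal cells, intercalated cells and macrophages and for strain were changed after first values were known. The tests on a blemish and on the neighbourhood of Gata2 were set before.

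Kallikrein 1 genes, tissue kallikreins that release kinins, were chosen after their values were seen. All 12 measured members were higher in the CKO cells, 11 of them at least 2-fold, with a median of 1.51 and the highest at 1.65. The direction held for every measured member under all alternatives, but 9 were at least 2-fold higher with normexp and 5 with spike-in scaling, with medians of 1.30 and 0.96. The members are near-identical in sequence and 1 abundant transcript can bind several probes, so the 12 values are not independent.

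Complement C3, Aldh1a3 and Mitf were also chosen after their values were seen. C3 was lower by a probe printed 10 times, at −3.32, and by its other probe, at −2.17. Aldh1a3, a retinaldehyde dehydrogenase, was higher by both probes, at 1.58 and 1.35. Mitf was at −3.33 by 1 probe and at −0.06 by the other.

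The cell type lists moved apart, with macrophage genes at −0.77, principal cell genes at −0.28 and intercalated cell genes at 0.62. Scaling that depends on signal is argued against. Under normexp, quantile normalization and cyclic loess the macrophage and intercalated medians stayed at least 0.42 from that of all genes, on opposite sides. A single factor per array moves all lists by the same amount and cancels in these distances, so it was not put to the test. A smaller share of principal cells alone would raise the genes of every other cell type alike. Such a change is argued against on these 2 arrays, since the intercalated and macrophage medians lay 1.38 apart (95% bootstrap interval over members 1.08 to 1.54). The interval covers list members, which can vary together, and not mice or preparations. The lists were known to lie apart when this condition was set. A larger share of intercalated cells cannot be told apart from higher expression in them. Of their 23 members 20 lay above the median of all genes and 73.9% within 0.54 of the list median, and markers of 1 type need not move alike. Fewer macrophages on the CKO array, through the purification or in the kidney, remain a candidate explanation for the macrophage list. DBA purification should remove such cells, however. The fall was not particular to macrophages. Fibroblast, podocyte, endothelial and proximal tubule lists, at −0.63, −0.50, −0.34 and −0.22, were also below their ranges. The thick ascending limb and loop list, at 0.30, was above its own. A fall of several cell types together was not tested. Of the 20 members of the macrophage list 95% lay within 0.54 of its median. That share says little by itself, since the quartiles of all genes, −0.12 and 0.23, lay within that distance of their median too. The list's abundant genes Lyz2 and Cd74, the latter named after its value was seen, were at 4.63 and 5.09 on the CKO array. On the WT array they were at 5.88 and 5.74. For the cytokine and injury lists, fewer macrophages cannot be told apart from lower expression in tubule cells. Of 42 members 2, Ccl2 and Fgb, lay below the limit of −2.01, and 3 were asked. That limit rests on the largest macrophage fall, that of the dim gene Itgam at −1.47, which came to −0.41 with normexp. Vcam1 and Cp, both at −1.98, lay just above the limit, so the count depends on this 1 gene. The genotype itself, which by its label leaves macrophages 1 Gata2 allele short, stays open as untested. Mice, purification and genotype change together between the 2 arrays.

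In 64 genes 1 probe was at least 2-fold lower while another stayed within 0.5, such as Sox5 at −3.53 and 0.20, and in 33 genes 1 probe was higher in the same way. A blemish is argued against, since 8 of the 71 lower probes had another within 5 rows and columns, at percentile 19.005 of 10000 random sets. Greater loss of 5' signal on the CKO array is argued against too, because the lower probe lay 5' of the unmoved one in 41 of 81 pairs, or 50.6% (95% Wilson interval 40.0 to 61.2, too narrow where pairs share a probe), where 80% was asked, and over 4332 mRNAs the CKO minus WT difference was larger at the 5' probe than at the 3' one by a median of 0.07. Random loss in amplification cannot be told apart from a change of transcript forms. The ratio of lower to higher genes was 1.94, between the 1.5 that equal loss was allowed and the 2 set to count against it. These limits made no allowance for the surplus of lower genes over all genes, 538 at 2-fold against 282 higher. That surplus moved with the scaling, so the ratio decides nothing here. No biological explanation was tested.

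Some genes were well above background on the CKO array only, led by Ifi202b at a bound of 4.11. Ifi202b and Ren2, at least 3.04-fold higher and near-identical to Ren1, are silent or absent in C57BL/6 mice, so a mixed strain background was weighed on 2 other genes not expressed or defective there: H2-Ea-ps was higher by at least 2.77 and Nnt by 1.08, with its 3 probes from 1.06 to 1.13. Both were thus at least 2-fold higher, but all of these values shrank with normexp. There H2-Ea-ps came to 1.07, Nnt to 0.99, Ifi202b to 2.08 and Ren2 to 0.75, and Nnt came to 0.53 with spike-in scaling. Strain cannot be told apart from genotype on 2 genes and 1 array per genotype. A stretch of another strain around Gata2 cannot be told apart from chance, since 16 of 252 genes within 20 Mb were 2-fold apart, 6.35% against 4.32% of all genes, at percentile 86.8 of random windows, and the 16 include Atp6v1b1, Slc6a6, Cd8a and Mitf. The labels name no strain.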
